A study of Homo sapiens with 28 samples.

How the data were processed

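Human H9 embryonic stem cells were profiled by Repli-seq in 2 settings. In an adherent course under Wnt and activin A, ESC, 6 h, 12 h, 24 h and 48 h had 2 replicates each. In an aggregate protocol, definitive endoderm, pancreatic progenitor, polyhormonal and beta-like cells had 1 profile each. Per the labels' protocols, cells were pulsed with BrdU, sorted into early and late S phase, and the BrdU-labelled DNA of each fraction was sequenced, so the 14 profiles rest on 28 libraries. The deposited file has a column per profile, with the log ratio of early over late signal at each position. The authors' log base is not written with the deposited values and was taken as log2, the usual choice for Repli-seq, per the labels' description of early and late fractions and the range of the values, -1.75 to 1.99. The submitters' processing notes name Bowtie2, SAMtools and bedtools without versions or roles, and the genome builds hg38 and mm10. Chromosome names and largest positions are those of human hg38. The notes state no normalization, smoothing or filter. From the values, the profiles share 1 distribution, with no more than 0.0411 between profiles at any rank. Positions 10 kb, 200 kb and 1 Mb apart on chromosome 1 correlate at 0.9995, 0.9057 and 0.418 (median over profiles), so neighbouring windows carry much the same value. A count of windows is a measure of sequence length and not of independent changes. Read depth per library cannot be had from ratios, so the limit that depth sets on precision is unknown.

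The column named for 0 h was taken as ESC. Of 287565 positions on 23 chromosomes (the autosomes and X), 287319 with a value in every profile were tested as deposited and 246 were left out. One model in limma 3.58.1 (R 4.3.3, with data.table in version 1.17.8) was fitted to all 14 profiles, with a mean per group, a single spread per window from 5 residual degrees of freedom and limma's moderation (3.33 prior degrees of freedom), and Benjamini-Hochberg adjustment over windows. A window was called at an adjusted p under 0.05 and a difference of at least 0.5. Each stage was compared with ESC, each time point with the one before, definitive endoderm with 48 h, and the 5 groups of the adherent course with an F test and a range of at least 0.5. A stretch is a run of called windows of one sign of at least 200 kb, bridging up to 100 kb without windows. The 3 steps between single profiles have no test and are given as windows that differ by at least 1 unit. To time the changes, windows were chosen as at least 1 unit from ESC replicate 1 in definitive endoderm and measured against ESC replicate 2, so that the choice and the measurement do not share a control. Shared calls between comparisons were set beside the number that independent calls would share, and correlations beside simulated unchanged groups with the same ESC profiles.

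Gene positions came from a RefSeq table of GRCh38.p14, the assembly of hg38. It gives no strand, so each gene took the window nearest to its midpoint, within 50 kb, in place of the planned start site. Of 19974 protein-coding genes with coordinates 19907 had such a window. The 9 gene lists (pluripotency, primitive streak and mesendoderm, definitive endoderm, pancreatic progenitor, endocrine and beta cell, hepatocyte and intestine, neuroectoderm, mesoderm and cardiovascular, housekeeping) had 272 entries, 271 of which matched a symbol. Lists share some genes, such as GATA6 and HNF4A. List shifts were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over 9 lists. The genes named are the called list genes, up to 3 per list and direction by size of difference, for each comparison with ESC. For 48 h, definitive endoderm and beta-like cells the 5 stretches per direction with the largest mean difference were added, with up to 2 genes each. A further 16 genes were to be given whatever they showed. The groups, lists, tests, thresholds, this rule and most alternatives were fixed before the data were examined. Genes named beside a count adjusted over the list alone, and genes of the closing section, were named after their values were seen. Not every gene the rule takes is printed.

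The procedure was tested on simulated data with the spread of these profiles (287319 windows). For 48 h it called 89.4% of windows changed by 0.75, 95.9% of those changed by 1, 99.5% of those changed by 1.5 and 100% of those changed by 2, and 4.72% of its calls were false. For definitive endoderm, with 1 profile, the shares were 64.5%, 87.8%, 97.1% and 100%, with 5.36% false. The simulated spread was independent between profiles and the same in the single profile, and no difference between protocols was simulated. The false shares hold under these settings alone. For 6 h, simulated without change, it made 0 calls. With 1 list moved by 0.5 at 48 h, camera over 19907 genes called that list and 1 other, which shares up to 6 genes with it. The noise in this list simulation was independent between windows, so it does not test the list calls under correlation between genes.

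Alternatives were quantile normalization, scaling of each profile by median and interquartile range, autosomes only, bins of 200 kb, no size threshold or 1 unit, the replicate number as a block, a trended and robust spread, fits of the groups compared alone, each replicate left out, other list tests, and ESC replicates exchanged. Added after seeing the data were leaving out sparsely listed windows (under 90% of positions within 500 kb listed) and the lower or higher end of each gene in place of its midpoint. Alternatives meant for counts per fraction had no use because the values are ratios. No genome sequence was held, so base composition was not checked. Transcription and Hi-C data of the series were not used here. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.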

Results

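Repli-seq measured when in S phase each part of the genome is copied, in H9 cells, an established line of human embryonic stem cells (ESC), on their way to endoderm and pancreas. Cells took up BrdU, a thymidine analogue built into new DNA, and were sorted by flow cytometry into an early and a late fraction of S phase, whose labelled DNA was sequenced. Each profile holds the log ratio of early over late signal at positions 10 kb apart, with the log base taken as 2, so that positive values stand for early and negative values for late replication. The series asks how replication timing changes beside transcription and genome folding when stem cells differentiate; transcription and folding were not analysed here. Adherent cells under Wnt and activin A gave 2 profiles each for ESC and for 6 h, 12 h, 24 h and 48 h. Cell aggregates carried through a pancreatic protocol gave 1 profile each for definitive endoderm, pancreatic progenitor, polyhormonal and beta-like cells. These 4 stages had no replicates, and their tests assume that they vary like the replicated groups. ESC and 48 h belong to the adherent setting, so protocol and stage cannot be told apart in comparisons with these 4 stages. A value was present in all 14 profiles at 287319 positions, called windows below, and 42.6% of the windows of a profile lay above 0. Across windows, which are not independent, the replicates correlated at r = 0.964 in ESC, 0.972 at 6 h, 0.964 at 12 h, 0.954 at 24 h and 0.935 at 48 h. The depth behind each value is unknown because the profiles hold no read counts. The labels do not say that the 2 replicates of a group came from separate cultures, so the p-values measure the spread between these profiles, which may be technical. Windows and genes are called earlier or later at an adjusted p under 0.05 (limma) and a difference of at least 0.5.

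The first comparison asked whether timing had moved within 6 h or 12 h of Wnt and activin A. POU5F1 (chromosome 6, 31164337 to 31170682, hg38), a core transcription factor of pluripotency, was early at 1.07 ± 0.065 (SD, n = 2) in ESC and differed from it by -0.04 at 6 h and by -0.12 at 12 h (adjusted p = 0.91 at 12 h). EOMES (chromosome 3, 27715953 to 27722713), a T-box factor of the primitive streak, was at 0.86 ± 0.021 in ESC and 1.15 ± 0.027 at 12 h (difference 0.29, SE 0.086, adjusted p = 0.52). GATA6 (chromosome 18, 22169589 to 22202528), a transcription factor of endoderm, lay 0.12 above ESC at 6 h and 0.54 above it at 12 h (SE 0.34, adjusted p = 0.88 at 12 h), or 0.85 without 12 h replicate 1 and 0.24 without 12 h replicate 2. FOXA2 (chromosome 20, 22580998 to 22585490), a pioneer factor of endoderm, lay 0.20 above ESC at 6 h and 0.44 above it at 12 h (SE 0.16, adjusted p = 0.63 at 12 h). No gene of the 9 fixed lists was called at either time. Adjusted over the list alone, SP5, a target of Wnt signalling on the primitive streak list, was earlier and SOX9 on the pancreatic progenitor list was later at 12 h. With limma, 0 of 287319 windows changed at 6 h, where 11534 had an unadjusted p under 0.05 and the smallest adjusted p was 0.441. With the replicate number as a block a few windows were called at 6 h (see the section on how the results depend on the processing). At 12 h 0 windows changed with limma, 19980 had an unadjusted p under 0.05 and the smallest adjusted p was 0.302.

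At 24 h the first calls of the main fit appeared. The fit with the replicate number as a block called more windows at 24 h (see the section on how the results depend on the processing). APELA (chromosome 4, 164877178 to 164899007), which encodes a peptide hormone of the early embryo, went from 1.09 ± 0.036 (SD, n = 2) in ESC to 0.04 ± 0.18 and was later (difference -1.04, SE 0.13, adjusted p = 0.049). It was the only list gene called, and its call ended without either ESC replicate and without either 24 h replicate (highest adjusted p = 0.32 with a profile left out), at the higher end of the gene, in bins of 200 kb and with a trended, robust spread. GATA6 stood at 0.50 ± 0.62 (difference 1.27, SE 0.34, adjusted p = 0.14). Across 14 alternatives its difference ran from 0.84 (without 24 h replicate 2) to 1.71, and 1 of them called it earlier. FOXA2 was 0.64 above ESC (SE 0.16, adjusted p = 0.12), and neither gene was called in the main fit. SOX17 (chromosome 8, 54457935 to 54460892), a transcription factor needed for definitive endoderm, was 0.44 above ESC (SE 0.20, adjusted p = 0.34). Among 19907 protein-coding genes, 1 was earlier (CLGN) and 3 were later (PCDH18, SNAP25 and APELA), of which CLGN, PCDH18 and SNAP25 are named after their values were seen. With p adjusted over the list alone, APELA and SOX9 were later and PCSK1, which encodes a prohormone convertase of endocrine cells, was earlier. Of the windows, 162 (0.0564%) changed, 49 earlier and 113 later, and 2 later stretches reached 200 kb. With limma 0 windows changed without ESC replicate 1, ESC replicate 2, 24 h replicate 1 or 24 h replicate 2, where 33912, 30970, 45386 and 28953 had an unadjusted p under 0.05. The 2-group fit of ESC and 24 h alone also gave 0, with 41774 at an unadjusted p under 0.05.

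**Figure D1:**
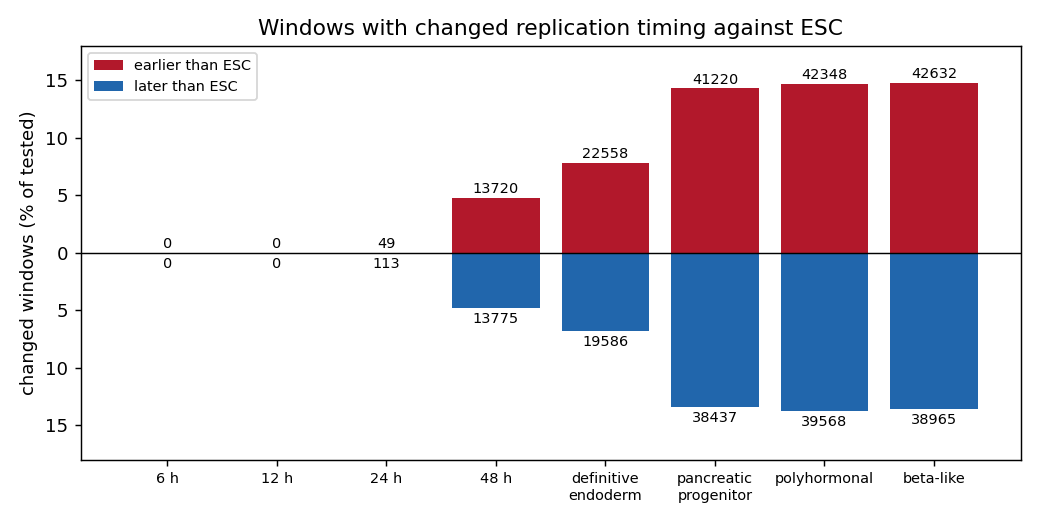
Share of the 287319 tested windows, in percent, that replicated earlier (bars upward, red) or later (bars downward, blue) than in ESC at each stage, with the number of windows at each bar. The share was 0 at 6 h and 12 h, 0.0564% at 24 h, 9.57% at 48 h and 27.7% to 28.5% at the 3 last stages.

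By 48 h GATA6, SOX17 and HNF4A were earlier, 3 of the 30 genes of the definitive endoderm list, of which 2 others were later. GATA6 reached 0.66 ± 0.55 (SD, n = 2), from -0.77 ± 0.021 in ESC (difference 1.43, SE 0.34, adjusted p = 0.033), and SOX17 reached 0.74 ± 0.52, from -0.15 ± 0.056 (difference 0.88, SE 0.20, adjusted p = 0.027). HNF4A (chromosome 20, 44355699 to 44434596), a nuclear receptor of liver and gut, went from 0.26 ± 0.084 to 0.81 ± 0.17 (difference 0.55, SE 0.13, adjusted p = 0.030). The GATA6 and HNF4A calls ended without ESC replicate 1, ESC replicate 2 or 48 h replicate 2 and the SOX17 call without either ESC replicate (highest adjusted p = 0.13, 0.13 and 0.12 with a profile left out). Without 48 h replicate 2 the SOX17 difference was 0.51, close to the size threshold. HNF4A was not called at the higher end of the gene or in bins of 200 kb (0.45, adjusted p = 0.052, and 0.37, adjusted p = 0.088). APELA, also on the definitive endoderm list, was at 0.16 ± 0.018 and later (difference -0.93, SE 0.13, adjusted p = 0.0073). FOXA2 (0.22, adjusted p = 0.39), GATA4 (chromosome 8, 11676935 to 11760002; -0.01) and EOMES (-0.24, SE 0.086, adjusted p = 0.10) were not called. Of the endocrine list, PCSK1 (chromosome 5, 96390333 to 96433248) went from -0.96 ± 0.058 to -0.02 ± 0.00071 and was earlier (difference 0.93, SE 0.11, adjusted p = 0.0062).

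The pluripotency genes called at 48 h were mostly later. DPPA2 (chromosome 3, 109293788 to 109316517) and its neighbour DPPA4 (chromosome 3, 109326144 to 109339636), which encode nuclear proteins of pluripotent cells, fell by 1.37 and 1.36 (SE 0.15 and 0.14, adjusted p = 0.0053 for both), from 0.74 ± 0.16 and 0.72 ± 0.14 in ESC to -0.63 ± 0.20 and -0.64 ± 0.17 (SD, n = 2). ZFP42 (chromosome 4, 187995771 to 188005246), also known as REX1 and a marker of pluripotent cells, fell by 1.51 (SE 0.25, adjusted p = 0.012), and its call ended without either ESC replicate (highest adjusted p = 0.065 with a profile left out). KLF4 (chromosome 9, 107484852 to 107489769), a reprogramming factor, was 0.53 earlier (SE 0.14, adjusted p = 0.041), a call that ended without ESC replicate 1, ESC replicate 2 or 48 h replicate 1 (highest adjusted p = 0.18 with a profile left out; 0.32 without 48 h replicate 1) and with a trended, robust spread. POU5F1 (0.96 ± 0.058), NANOG (chromosome 12, 7789402 to 7799146; difference 0.04, adjusted p = 0.83) and SOX2 (chromosome 3, 181711925 to 181714436; difference -0.78, SE 0.25, adjusted p = 0.081) were not called. SOX2 was called later without 48 h replicate 1 (-1.1, adjusted p = 0.035) and with a trended, robust spread (adjusted p = 0.048), and its difference was -0.45 without 48 h replicate 2. NKX6-1 (chromosome 4, 84491985 to 84499292), a transcription factor of beta cells, was later at 48 h (difference -0.93, SE 0.12, adjusted p = 0.0066). NEUROG1 (chromosome 5, 135534282 to 135535964), a neural factor, was earlier (difference 0.71, SE 0.10, adjusted p = 0.0085).

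By list, 1 of 26 pluripotency genes was earlier and 4 were later at 48 h, with 1 earlier and 0 later of 26 primitive streak genes, 3 and 2 of 30 definitive endoderm genes, 2 and 4 of 28 pancreatic progenitor genes and 1 and 3 of 37 endocrine genes. Of the hepatocyte and intestine list 1 of 24 was earlier, of the neuroectoderm list 3 of 36 were earlier and 5 later, and of the mesoderm list 2 of 35 were later. With limma 0 of 29 housekeeping genes changed, 4 having an unadjusted p under 0.05. Adjusted over the list alone, 6 neuroectoderm genes and 1 mesoderm gene were later, and the other counts were the same. As groups, the definitive endoderm list (median difference 0.17, camera adjusted p = 0.071), the neuroectoderm list (-0.21, adjusted p = 0.071) and the pluripotency list (-0.11, adjusted p = 0.075) stayed above the threshold. With 10000 random lists matched on timing in ESC, the median of the definitive endoderm list lay at percentile 99.9 (adjusted p = 0.0054) and that of the neuroectoderm list at percentile 0 (adjusted p = 0.0018). Without 48 h replicate 1, camera called these 2 lists. Over all profiles each had adjusted p = 0.42 with an estimated correlation. The other camera values were adjusted p = 0.17 for housekeeping, 0.26 for pancreatic progenitor and 0.80 for the primitive streak, endocrine, hepatocyte and intestine, and mesoderm lists. The test for the primitive streak list pointed down with a mean of 0.03 and a median of -0.10, and that for the hepatocyte list pointed up with a median of -0.01.

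Among the stretches of changed windows at 48 h, that around GATA6 and CTAGE1 (chromosome 18, 21930000 to 22640000) had the largest mean shift to earlier, from -0.59 ± 0.064 in ESC to 0.63 ± 0.26 at 48 h (SD, n = 2; difference 1.22). CTAGE1 itself (chromosome 18, 22413599 to 22417915) was 1.61 earlier (SE 0.20, adjusted p = 0.0066). A stretch with RGS22 (chromosome 8, 99880000 to 100380000) was 1.19 earlier and one with BMP2 (chromosome 20, 6360000 to 6880000), a growth factor gene, was 1.12 earlier, with the BMP2 gene call ending without ESC replicate 1, ESC replicate 2 or 48 h replicate 2 (highest adjusted p = 0.12 with a profile left out). The stretch on chromosome 5 from 156390000 to 157000000, with PPP1R2B and TIMD4, fell by 1.61, from 0.63 ± 0.33 to -0.98 ± 0.25. PPP1R2B (chromosome 5, 156850295 to 156852528) fell by 1.76 (SE 0.16, adjusted p = 0.0042). A stretch on chromosome 4 from 187850000 to 188280000 holds ZFP42, TRIML2 and TRIML1 and fell by 1.43.

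Of all windows, 27495 (9.57%) changed by 48 h, 13720 earlier and 13775 later, or 137.2 Mb and 137.8 Mb. There were 266 earlier and 280 later stretches of at least 200 kb, and 663 earlier and 631 later genes. Late windows that became early numbered 5399 and early windows that became late numbered 5976. Without ESC replicate 1 the count was 6178 and without ESC replicate 2 it was 7556. The fit of ESC and 48 h alone, in which the spread rests on 4 profiles, gave 0 with limma and 68227 at an unadjusted p under 0.05.

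**Figure D2:**
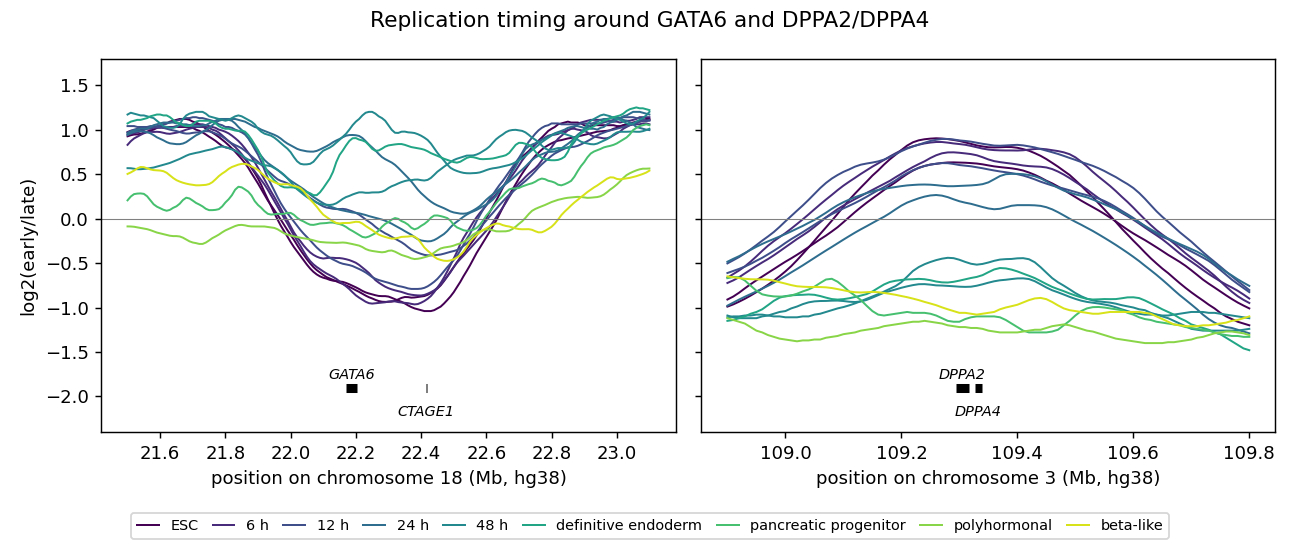
Log2 of early over late signal (vertical axis) along chromosome 18 around GATA6 and CTAGE1 and along chromosome 3 around DPPA2 and DPPA4 (horizontal axis, Mb, hg38), 1 line per profile coloured by stage, with replicates in the same colour and genes as black bars. GATA6 went from -0.77 in ESC to 0.66 at 48 h and 0.90 in definitive endoderm, while DPPA2 went from 0.74 to -0.63 and -0.68.

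Definitive endoderm from the aggregate protocol was set against ESC to ask what the endoderm state shares with the adherent course. GATA6 was at 0.90 (difference 1.67, SE 0.42, adjusted p = 0.032), SOX17 at 1.02 (difference 1.17, SE 0.24, adjusted p = 0.017) and SLC5A9 (chromosome 1, 48222716 to 48248638), a sugar transporter gene of the definitive endoderm list, at 0.99, from -0.45 ± 0.054 (SD, n = 2; difference 1.45, SE 0.30, adjusted p = 0.017), all 3 earlier. Their calls ended without either ESC replicate (highest adjusted p = 0.095, 0.063 and 0.063 with a profile left out), and that of GATA6 also in bins of 200 kb (adjusted p = 0.058). FGF2 (chromosome 4, 122826682 to 122898236), the growth factor that sustains human stem cells, went from 1.27 ± 0.10 to -0.27 and was later (difference -1.55, SE 0.12, adjusted p = 0.0031). DPPA2 fell by 1.43 (SE 0.18, adjusted p = 0.0040) and APELA fell by 1.32 (SE 0.15, adjusted p = 0.0037). TFF3 (chromosome 21, 42311667 to 42315409), a gene of gut mucus, went from -0.20 ± 0.054 to 1.14 and was earlier (difference 1.34, SE 0.19, adjusted p = 0.0053). PCSK1 was 1.24 earlier (SE 0.14, adjusted p = 0.0036) and APOB (chromosome 2, 21001429 to 21044073), the apolipoprotein of liver and gut, 0.90 earlier (SE 0.16, adjusted p = 0.011). NEUROG3 (chromosome 10, 69571485 to 69573422), which starts the endocrine programme, was 0.72 earlier (SE 0.14, adjusted p = 0.014), a call that ended without ESC replicate 1 (highest adjusted p = 0.061 with a profile left out) and fell under the size threshold in bins of 200 kb (0.49). FOXA2 (difference 0.57, SE 0.20, adjusted p = 0.083) and EOMES (-0.33, SE 0.10, adjusted p = 0.067) were not called, though FOXA2 was in bins of 200 kb (0.73, adjusted p = 0.034).

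Genes of other lineages moved as well in definitive endoderm. LMX1A (chromosome 1, 165201867 to 165356715), a factor of dopaminergic neurons, was 1.26 earlier (SE 0.15, adjusted p = 0.0038), IRX3 (chromosome 16, 54283304 to 54286787), a homeobox gene of the neural tube, 1.13 earlier (SE 0.18, adjusted p = 0.0072), and DLX5 (chromosome 7, 97020396 to 97024831), a homeobox gene of bone and forebrain, fell by 1.12 (SE 0.21, adjusted p = 0.011). EEF1A1 (chromosome 6, 73515750 to 73521032), a translation factor on the housekeeping list, went from 1.16 ± 0.081 (SD, n = 2) to 0.32 and was later (difference -0.85, SE 0.12, adjusted p = 0.0048). Of the lists, 10 of 30 definitive endoderm genes were earlier and 2 later, with 1 and 6 of 26 pluripotency genes, 0 and 1 of 26 primitive streak genes, 3 and 2 of 28 pancreatic progenitor genes and 4 and 2 of 37 endocrine genes. Among 24 hepatocyte and intestine genes 3 were earlier and 1 later, among 36 neuroectoderm genes 7 and 5, among 35 mesoderm genes 1 and 1, and among 29 housekeeping genes 0 and 4. When adjusted over the list alone, 11 definitive endoderm genes (with FOXA2) and 8 neuroectoderm genes were earlier, and the other counts were the same. No list passed camera: adjusted p = 0.069 for the definitive endoderm list (median 0.09), 0.069 for pluripotency (-0.09), 0.073 for housekeeping (-0.11), 0.25 for endocrine, 0.33 for pancreatic progenitor, 0.55 for hepatocyte and intestine, 0.61 for mesoderm, 0.79 for neuroectoderm and 0.93 for primitive streak. Test and median differed in sign for the hepatocyte list (up, median -0.02), and test and mean for the primitive streak list (down, mean 0.04) and the mesoderm list (up, mean -0.0036). With the lower end of each gene in place of the midpoint, 2 lists passed, pluripotency and definitive endoderm (at the midpoint both had adjusted p = 0.37 with an estimated correlation).

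In definitive endoderm 42144 windows (14.7%) changed, 22558 earlier and 19586 later, in 383 and 347 stretches of at least 200 kb, and 1066 genes were earlier and 1351 later. A stretch on chromosome 4 from 122540000 to 123050000 with FGF2 and NUDT6 fell by 1.42, and one on chromosome 1 from 115960000 to 116350000 with SLC22A15 and MAB21L3 was 1.38 earlier. The largest mean shift to earlier (1.55) was on chromosome 8 from 44840000 to 45580000, where 57 positions are listed over 750 kb and no protein-coding gene lies. Without ESC replicate 1 the count was 23150 and without ESC replicate 2 it was 21515.

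Set against 48 h directly, definitive endoderm differed in 11 windows, 1 stretch on chromosome 8 from 45190000 to 45330000, where its value was 1.86 against -0.62 ± 0.034 (SD, n = 2) at 48 h (adjusted p between 0.036 and 0.050). With limma the count was 0 without 48 h replicate 1 (40484 at an unadjusted p under 0.05) and 0 without 48 h replicate 2 (51393), and it was 0 with sparsely listed windows left out (37761). It was also 0 in the fit of these 2 groups alone (15543). With the replicate number as a block, and the single profile coded as replicate 1 without a label for it, more windows were called (see the section on how the results depend on the processing). Of the 13720 windows earlier at 48 h, 9170 (66.8%) were earlier in definitive endoderm, where independent calls would share 1077, and of the 13775 later ones 9126 (66.3%) were later there, against 939. No window was called in opposite directions. Across windows the 2 sets of differences correlated at r = 0.806 (covariance 0.128). Unchanged groups simulated against the same ESC profiles gave r = 0.406 and a covariance of 0.012. With 1 ESC replicate for each comparison the values were 0.672 and 0.115, and since each then rests on 1 control profile, part of the excess in shared calls may come from the shared controls.

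The next question was when during the adherent course the changes seen in definitive endoderm arose. Windows at least 1 unit from ESC replicate 1 in definitive endoderm were measured against ESC replicate 2. Among the 6896 earlier windows, which include GATA6, the median difference was -0.001 ± 0.051 (SD, n = 2) at 6 h, 0.05 ± 0.074 at 12 h, 0.28 ± 0.11 at 24 h and 0.66 ± 0.15 at 48 h, or 59.3% of the 1.11 in definitive endoderm. Among the 6135 later windows, which include DPPA2, it was -0.05 ± 0.13, -0.09 ± 0.20, -0.34 ± 0.15 and -0.71 ± 0.13, or 66.8% of the -1.06 in definitive endoderm. In beta-like cells the earlier windows stood at 0.65 and the later windows at -1.06. With the ESC replicates exchanged, the medians were 0.59 and -0.61 at 48 h and 0.49 and -0.96 in beta-like cells. The windows were chosen on the same definitive endoderm profile that serves as the reference. Its medians may thus be inflated, which would make the shares at 48 h too low. Definitive endoderm also came from the other protocol, so the shares do not measure progress along a single course.

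**Figure D3:**
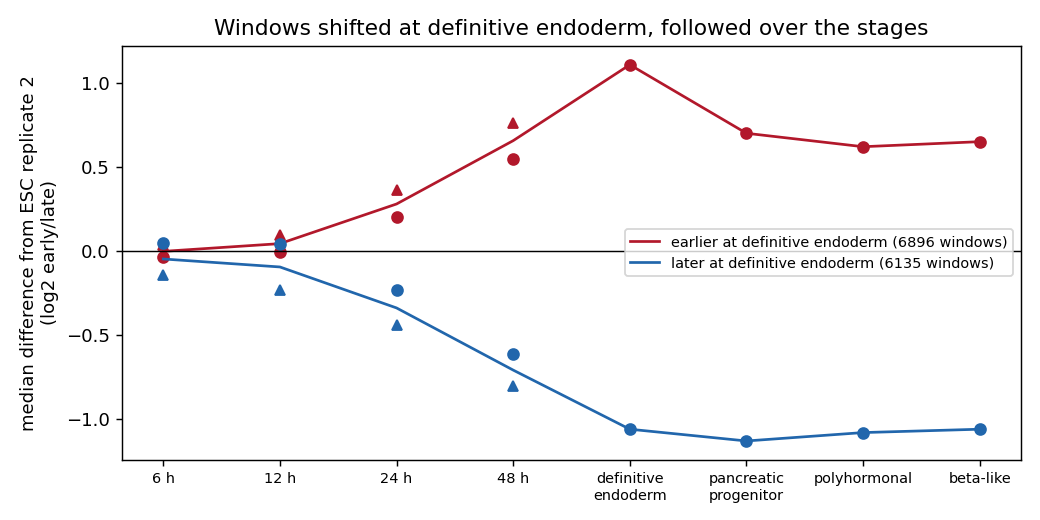
Median difference from ESC replicate 2 (log2 units) at each stage for 6896 windows that were earlier and 6135 that were later in definitive endoderm than in ESC replicate 1. Circles are replicate 1 or a single profile, triangles are replicate 2 and lines join the means, which at 48 h were 0.66 and -0.71.

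Over the whole adherent course an F test in limma asked which windows varied at any time. It called 10797 windows (3.76%). The count was 0 without 6 h replicate 1, 6 h replicate 2 or 48 h replicate 2 (50956, 52540 and 61923 at an unadjusted p under 0.05 in limma). It was 289 without ESC replicate 1, 235 without ESC replicate 2, 2420 and 4058 without either 12 h replicate, 6522 and 3388 without either 24 h replicate. From one time to the next limma called 0 windows between 6 h and 12 h (8256 at an unadjusted p under 0.05), 0 between 12 h and 24 h (13535) and 0 between 24 h and 48 h (41239, smallest adjusted p 0.0996). With the replicate number as a block, windows were called from 24 h to 48 h and the F test called more (see the section on how the results depend on the processing). Without 48 h replicate 1 the step from 24 h to 48 h had 3857 windows. CTAGE1, next to GATA6, stood at -0.59 at 12 h, -0.02 at 24 h and 0.66 at 48 h.

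Pancreatic progenitors, polyhormonal and beta-like cells were set against ESC to follow the lineage beyond endoderm. They differ from ESC in protocol as well as in stage, and the comparison cannot separate these. In pancreatic progenitors INS (chromosome 11, 2159779 to 2161209), the insulin gene, went from -0.60 ± 0.14 (SD, n = 2) to 0.85 and was earlier (difference 1.46, SE 0.18, adjusted p = 0.00097). SOX9 (chromosome 17, 72121020 to 72126416), a factor of pancreatic progenitors, was 0.92 earlier (SE 0.12, adjusted p = 0.0012). EOMES fell by 1.71 (SE 0.10, adjusted p = 0.00022), NANOG fell by 0.91 (SE 0.14, adjusted p = 0.0020), PAX6 (chromosome 11, 31789026 to 31817961), an eye and islet factor, fell by 1.1 (SE 0.15, adjusted p = 0.0012) and FOXA2 fell by 0.90 (SE 0.20, adjusted p = 0.0096). PDX1 (chromosome 13, 27920000 to 27926313), the main regulator of pancreas formation, was later (difference -1.1, SE 0.29, adjusted p = 0.020), a call that ended without either ESC replicate (highest adjusted p = 0.074 with a profile left out). GATA6 (difference 0.63, adjusted p = 0.29) and SOX17 (-0.67, adjusted p = 0.066) were not called, though both were in the fit of the 2 groups alone (adjusted p = 0.026 and 0.024). Counts earlier and later were 1 and 11 of 26 for pluripotency, 3 and 3 of 26 for primitive streak, 3 and 8 of 30 for definitive endoderm, 4 and 6 of 28 for pancreatic progenitor, 9 and 6 of 37 for endocrine, 5 and 5 of 24 for hepatocyte and intestine, 6 and 13 of 36 for neuroectoderm, 5 and 4 of 35 for mesoderm and 0 and 4 of 29 for housekeeping. Adjusted over the list alone, 14 neuroectoderm and 3 housekeeping genes were later and the other counts were the same. Over all protein-coding genes with a window, 10.8% were earlier and 11.8% later, and several list counts lie near these shares. Of the windows 79657 (27.7%) changed, 41220 earlier and 38437 later, with the balance turned at a threshold of 1 unit (11914 and 15330).

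Polyhormonal cells, which hold several islet hormones at once, had INS at 0.95 (difference 1.55, SE 0.18, adjusted p = 0.00058) and SOX9 1.3 earlier (SE 0.12, adjusted p = 0.00025). NEUROG3 was 0.86 earlier (SE 0.14, adjusted p = 0.0027) and NCAM1 (chromosome 11, 112961420 to 113278436), a cell adhesion gene of neurons and endocrine cells, 1.56 earlier (SE 0.18, adjusted p = 0.00047). FABP1 (chromosome 2, 88122982 to 88128062), a fatty acid carrier of liver and gut, fell by 1.61 (SE 0.15, adjusted p = 0.00024) and EOMES fell by 2.00 (SE 0.10, adjusted p = 8.7e-05). SST (chromosome 3, 187668912 to 187670394), the somatostatin gene, was later (difference -0.69, SE 0.21, adjusted p = 0.033), a call that ended without either ESC replicate (highest adjusted p = 0.11 with a profile left out) and in bins of 200 kb. GCG (chromosome 2, 162142882 to 162152247), the glucagon gene, was late in ESC at -1.07 ± 0.028 (SD, n = 2) and was not called (difference -0.21, adjusted p = 0.34). Counts earlier and later were 0 and 14 of 26 for pluripotency, 2 and 4 of 26 for primitive streak, 0 and 12 of 30 for definitive endoderm, 4 and 5 of 28 for pancreatic progenitor, 6 and 11 of 37 for endocrine, 7 and 7 of 24 for hepatocyte and intestine, 9 and 7 of 36 for neuroectoderm, 5 and 8 of 35 for mesoderm and 0 and 4 of 29 for housekeeping. When adjusted over the list alone, KIT, a receptor gene of the definitive endoderm list, was earlier and SOX17 joined the later genes (1 and 13), and the other counts were the same. Over all protein-coding genes with a window, 10.4% were earlier and 13.6% later. Of the windows 81916 (28.5%) changed, 42348 earlier and 39568 later (15261 and 15403 at a threshold of 1 unit).

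In beta-like cells INS was at 0.78 (difference 1.38, SE 0.18, adjusted p = 0.0010) and ABCC8 (chromosome 11, 17392498 to 17476845), part of the potassium channel that triggers insulin release, was 0.95 earlier (SE 0.13, adjusted p = 0.0010). ERO1B (chromosome 1, 236215101 to 236281958), which helps insulin to fold, was 1.06 earlier (SE 0.18, adjusted p = 0.0030). Other genes of mature islets were later: CHGB (chromosome 20, 5911510 to 5925353), a granule protein gene, fell by 0.98 (SE 0.12, adjusted p = 7e-04), NKX6-1 fell by 0.90 (SE 0.14, adjusted p = 0.0024) and PDX1 fell by 1.46 (SE 0.29, adjusted p = 0.0058), to -0.71. APOB rose from -1.11 ± 0.069 (SD, n = 2) to 1.00 and was earlier (difference 2.11, SE 0.16, adjusted p = 0.00016). DPPA2 and NANOG of the pluripotency list, EOMES and APELA were later, with DPPA2 at -1.81 (SE 0.18, adjusted p = 0.00032), NANOG at -0.98 (SE 0.14, adjusted p = 0.0012), EOMES at -1.81 (SE 0.10, adjusted p = 0.00014) and APELA at -1.74 (SE 0.15, adjusted p = 0.00022) relative to ESC. POU5F1 (1.05, adjusted p = 0.90), SOX2 (difference -0.49, adjusted p = 0.27), GATA6 (0.73, adjusted p = 0.23), FOXA2 (-0.46, adjusted p = 0.11), GCG (-0.29, adjusted p = 0.19) and TBXT (chromosome 6, 166157656 to 166168655; 0.02), a primitive streak factor, were not called. GATA4 (-0.39, adjusted p = 0.046) and PAX6 (-0.48, adjusted p = 0.037) passed the p threshold but not the size threshold. In the fit of the 2 groups alone GATA6 was called earlier (adjusted p = 0.018). SST was later (difference -0.63, adjusted p = 0.046), a call that ended without either ESC replicate (highest adjusted p = 0.15 with a profile left out) and in bins of 200 kb.

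As groups, 0 of 26 pluripotency genes were earlier and 14 later in beta-like cells (15 had an unadjusted p under 0.05 in limma), a shift to later by camera (median -0.76, adjusted p = 0.00023; adjusted p = 0.13 with an estimated correlation). Of 30 definitive endoderm genes 0 were earlier and 13 later (median -0.42, camera adjusted p = 0.025; adjusted p = 0.55 with an estimated correlation). With an estimated correlation no camera call held in any comparison. Counts earlier and later were 2 and 4 of 26 for primitive streak (camera adjusted p = 0.87), 5 and 4 of 28 for pancreatic progenitor (0.47), 9 and 7 of 37 for endocrine (0.93) and 6 and 8 of 24 for hepatocyte and intestine (0.87). They were 9 and 6 of 36 for neuroectoderm (0.99), 4 and 5 of 35 for mesoderm (0.87) and 0 and 3 of 29 for housekeeping (0.47). Adjusted over the list alone, endocrine had 8 later, neuroectoderm 7 later, mesoderm 6 later and housekeeping 2 later, and the other counts were the same. Over all protein-coding genes with a window, 10.9% were earlier and 13.4% later. Signs differed for the primitive streak list (test down, median 0.02), the endocrine list (test up, median -0.05, mean -0.01), the hepatocyte list (test up, median and mean -0.02) and the mesoderm list (test up, mean -0.01).

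The stretches with the largest shifts in beta-like cells held other genes. A stretch of chromosome 2 from 16280000 to 17180000 with CYRIA, a regulator of the actin skeleton, was 1.68 earlier, and CYRIA itself (chromosome 2, 16549459 to 16665834) went from -1.06 ± 0.13 (SD, n = 2) to 1.08 (difference 2.15, SE 0.15, adjusted p = 0.00015). A stretch of chromosome X from 113590000 to 116070000 with PLS3 and LUZP4 fell by 1.82, and PLS3 (chromosome X, 115561174 to 115650861), an actin bundling gene, went from 1.18 ± 0.050 to -0.98 (difference -2.16, SE 0.12, adjusted p = 0.00014). A stretch of chromosome 5 from 116100000 to 117180000 with SEMA6A, an axon guidance gene, fell by 1.72. Of the windows 81597 (28.4%) changed, 42632 earlier and 38965 later (14251 and 15121 at a threshold of 1 unit), in 671 and 632 stretches of at least 200 kb. Of the windows earlier in definitive endoderm 11196 of 22558 (49.6%) were earlier in beta-like cells, where independent calls would share 3347, and of the later ones 12352 of 19586 (63.1%) were later, against 2656. Opposite calls numbered 477 and 490. These comparisons use the same ESC profiles, so part of this excess too may come from them, and the difference between both shares was not tested here.

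**Figure D4:**
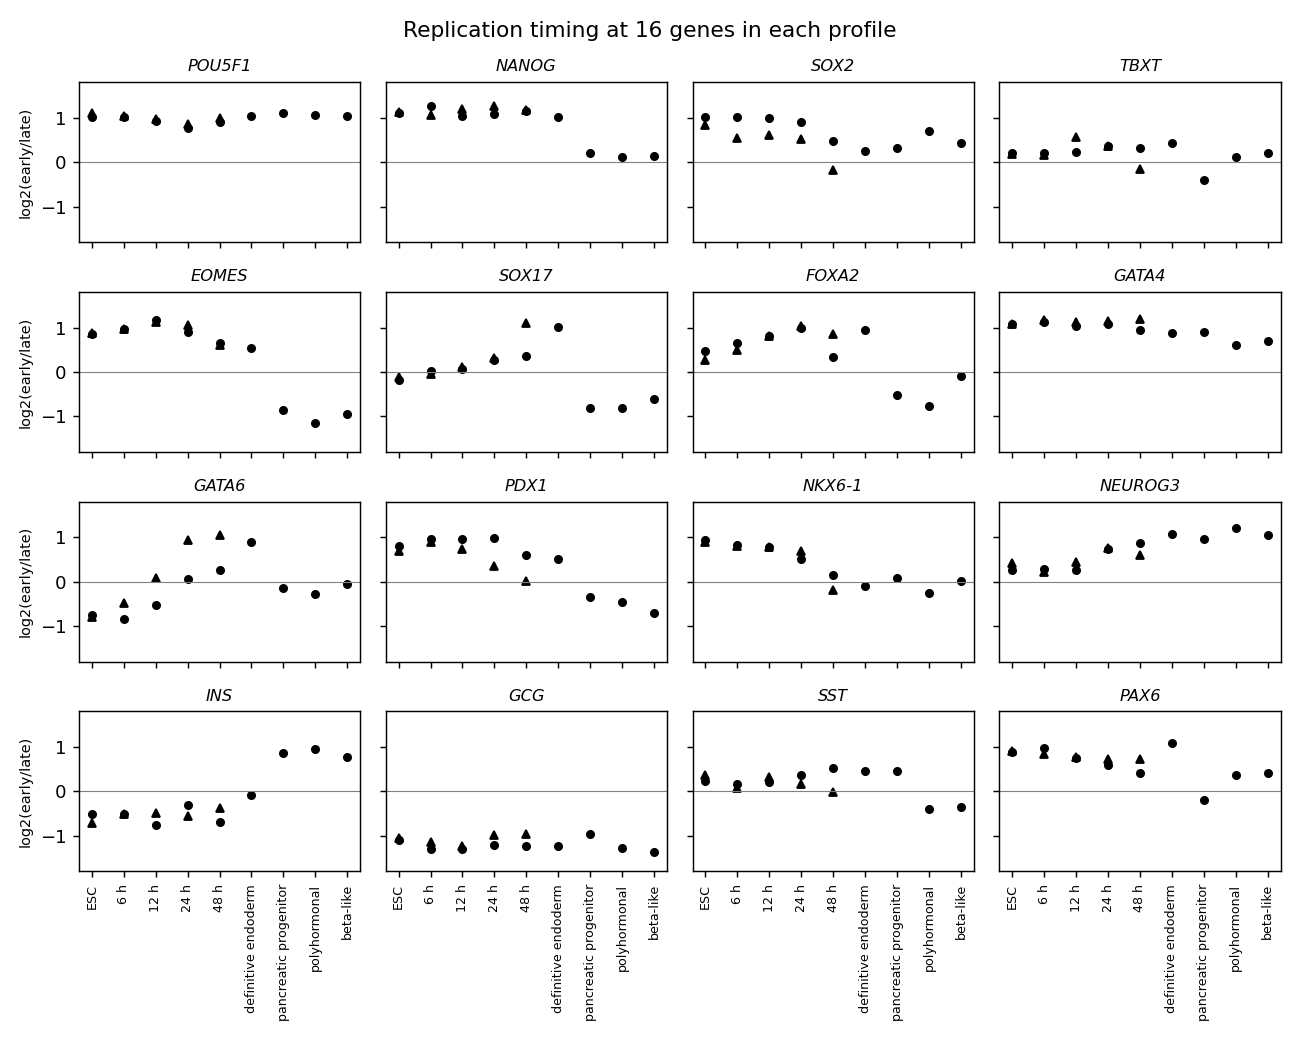
Log2 of early over late signal (vertical axis) for 16 genes given whatever they showed, in each profile from ESC to beta-like cells (horizontal axis), with circles for replicate 1 or a single profile and triangles for replicate 2. INS went from -0.60 in ESC to 0.78 in beta-like cells, EOMES from 0.86 to -0.95, and POU5F1 stayed between 0.96 and 1.11 in the stage means from 48 h on.

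Between the aggregate stages, which have 1 profile each, differences are values without a test. From definitive endoderm to pancreatic progenitor 15139 windows (5.27%) differed by at least 1 unit, 6767 to earlier and 8372 to later, and EOMES went from 0.53 to -0.85. From pancreatic progenitor to polyhormonal 9526 windows (3.32%) differed by that much, and SST went from 0.46 to -0.40. From polyhormonal to beta-like 669 windows (0.233%) differed by 1 unit, with SOX2 at 0.71 and then 0.45. For scale, replicate pairs differed by that much in 0.185% of windows in ESC and 0.405% at 48 h.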

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

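The test of library differences between replicates, the test on 48 h alone, the test on both sets of windows and the tests against the 48 h change were chosen only after the result was seen. Each SE in this section is from a jackknife that leaves out each chromosome in turn. It measures spread between chromosomes within the same profiles, and not spread between replicates or cultures. One result met a rule for a closer look because a test of the difference between groups, definitive endoderm against 48 h, called it: 11 windows changed, all of them earlier and all on chromosome 8.

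The 11 windows (chromosome 8, 45190000 to 45330000) stood at 1.86 in definitive endoderm, -0.62 ± 0.034 (SD, n = 2) at 48 h, -1.47 in pancreatic progenitors, -0.55 in polyhormonal and 0.19 in beta-like cells. Between 77.2% and 78.2% of the positions within 500 kb of them are listed, which makes them sparsely listed. Across replicate pairs, sparsely listed windows differed by at least 1 unit in 1.9% of cases and others in 0.174%, a ratio of 10.9 (jackknife SE 6.3). Both conditions set beforehand for noise next to a gap in the positions were met, a ratio above 5 and sparsely listed windows. The ratio also lay within 2 SE of 1, which stands for no difference, and the stage has 1 profile. Such noise and a difference in cells thus cannot be told apart here. No biological explanation was tested.

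Along the line from ESC to definitive endoderm, replicate 2 stood ahead of replicate 1 at each time point. Replicates 1 and 2 stood at 3.65% and 10.7% at 6 h and at 7.94% and 20.5% at 12 h. They stood at 29.2% and 38.4% at 24 h and at 57.4% and 70.3% at 48 h. The gap at 12 h (12.6 points, SE 1.3) was close to that at 48 h (12.9 points, SE 1.8). Each placing is measured from an ESC profile that also defines the line, so noise in that profile raises it even without change. The gaps at 6 h and 12 h therefore do not show that the cells had moved apart by then. A second line, from the mean of 6 h and 12 h to definitive endoderm, leaves ESC out, but cannot place 6 h and 12 h themselves. Along it, each measured against its own ESC profile, the replicates at 24 h and 48 h differed by at least 8.83 percent (SE 1.5). This argues against a fixed difference between replicate 1 and replicate 2 libraries that is present in ESC too. A library difference that began only after ESC was not tested. A noisier replicate 1 was predicted to have a larger off-course spread than replicate 2 at 24 h and 48 h. Its spread was 0.801 times that of replicate 2 at 24 h (SE 0.016) and, at 48 h alone, 1.12 times (SE 0.017). Off-course spread also holds real change off the line and noise of the ESC profile, so it cannot decide on noise. Noise in replicate 1 thus stays open at both times. Along the second line the gap at 24 h and 48 h was at least 8.71 percent (SE 2), both in windows that became earlier and in those that became later. Cells of replicate 2 further along a single course may therefore account for it. This is a hypothesis, and neither culture nor sorting records were held to tell cells from handling.

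Windows earlier in definitive endoderm kept 58.8% of their change in beta-like cells, while windows later there kept 100%, a difference of 41.5 points (jackknife SE 8.3). With the ESC replicates exchanged in choice and measurement, the shares were 44.6% and 91.6%. The SE does not cover this dependence on the ESC replicate. A general drift of windows with the same timing in ESC is argued against, as the difference was 45.3 points (SE 5.5) after subtracting matched windows. Relative to their change at 48 h, which took no part in the choice, earlier windows kept 97.3% (SE 12) and later ones 152%, a difference of 54.3 points (SE 14). Values inflated by the choice of windows are thereby argued against as the source of the difference between both kinds. They are not argued against as the source of the part-way return, since 48 h lay short of definitive endoderm. The share of earlier windows against 48 h also lay within 2 SE of 100%. With the ESC replicates exchanged, the earlier windows stood at 0.49 in beta-like cells and 0.59 at 48 h, without a test. With windows chosen on 48 h replicate 1, both kinds kept 106% (difference 0.26 points, SE 23), so the dependence on windows chosen on the single definitive endoderm profile also stays open.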

How the results depend on the processing

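All counts are percent of tested windows. None of the 232 called values of named genes reversed sign under the alternatives run, but the balance of earlier and later windows did in some counts. At a size threshold of 1 the earlier share of changed windows went from 51.7% to 43.7% in pancreatic progenitor, from 51.7% to 49.8% in polyhormonal and from 52.2% to 48.5% in beta-like cells, and the cause was not tested. At 48 h it was 49.9% and ran from 42% (without ESC replicate 1), 42.7% (a threshold of 1) and 48.3% (without ESC replicate 2) to 51.9% (autosomes only), 55.5% (without 48 h replicate 2) and 56.3% (without 48 h replicate 1), with the other alternatives that made calls between 49.5% and 50.5%, so neither direction led throughout. From polyhormonal to beta-like it was 49.8%, 50.4% on autosomes only and 28.9% (132 earlier, 324 later) with sparsely listed windows left out. Sparsely listed windows left out and the ends of genes were added after seeing the data. Quantile normalization and median and interquartile scaling ended no call of a named gene, which says little, because the profiles already shared 1 distribution. Alternatives meant for counts per fraction were not run because the values are ratios, and the limit that depth sets is unknown. The labels give the replicates only a shared number. Replicate differences correlated between groups at -0.014 for ESC and 48 h. For all other pairs the correlation lay between 0.19 (ESC and 24 h) and 0.6 (6 h and 12 h). Profiles of the same number thus shared part of their deviation, which the main fit does not use. With a replicate block the count went to 0.0181 (52 windows) at 6 h, 3.31 at 24 h, 22.4 in definitive endoderm, 1.39 for 48 h against 24 h, 1.45 for definitive endoderm against 48 h and 12.9 in the F test, and 2 lists passed at 48 h (definitive endoderm and neuroectoderm). The block coded the 4 single profiles as replicate 1, although their columns carry no replicate number and they come from the other protocol. The block values for definitive endoderm rest on that assignment, which nothing in the labels backs.

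A size threshold of 1 gave 0.0237 at 24 h, 1.24 at 48 h, 3.59 in definitive endoderm, 9.48 in pancreatic progenitor, 10.7 in polyhormonal and 10.2 in beta-like cells and 1.02 in the F test, fewer in total by construction. A size threshold of 0.5 in the untested steps gave 26.2 from definitive endoderm to pancreatic progenitor, 20.2 on to polyhormonal and 7.61 on to beta-like, and in the timing of changes medians of 0.42 (earlier, 48 h), -0.174 (later, 24 h) and -0.408 (later, 48 h), also by construction. For definitive endoderm against 48 h, bins of 200 kb gave 0.0138, a trended and robust spread 0.0679, sparsely listed windows left out 0 (37761 windows at an unadjusted p under 0.05 in limma), since all called windows are of that kind. Fits of only the 2 groups compared, with fewer profiles to estimate the spread, gave 0 at 24 h, 0 at 48 h and 0 for definitive endoderm against 48 h (41774, 68227 and 15543 at an unadjusted p under 0.05), and lay within 1.5 times for the other stages against ESC.

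With 1 replicate left out, where the lone profile is assumed to vary like the other groups, the range was 0 to 0 at 24 h, 2.15 to 11 at 48 h, 7.49 to 8.06 in definitive endoderm, 21.9 to 23.3 in pancreatic progenitor, 23.3 to 24.3 in polyhormonal, 23.2 to 24.2 in beta-like, 0 to 1.34 for 48 h against 24 h, 0 to 0 for definitive endoderm against 48 h and 0 to 2.69 in the F test. Fewer profiles are part of the construction; what else moved these counts was not tested. For the gene lists at 48 h, 10000 random lists gave 2, the higher end of each gene 1 and leaving out 1 replicate 0 to 2. In definitive endoderm the lower end of each gene gave 2 lists, and in beta-like cells an estimated correlation gave 0. The cause was not tested.

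Of 232 called values of named genes, bins of 200 kb ended 33, the fits of only the 2 groups 53, the lower end of the gene 13, the higher end 10, a trended and robust spread 5 and the replicate block 2. Leaving out 1 replicate ended 163 of 542. Of 97 values of named genes that were not called, bins of 200 kb called 1, the fits of only the 2 groups 6, the higher end of the gene 1, a trended and robust spread 1 and the replicate block 9, and leaving out 1 replicate called 2 of 316.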

Other observations

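Gene families were compared with 2000 circular shifts of their windows along all tested windows of the genome, for 21 families in 2 comparisons. The families were chosen after the main results were seen. Shifted windows were not matched on gene density or timing in ESC, so the test does not contrast a family with other genes. In definitive endoderm, zinc finger genes of the ZNF family, which encode DNA-binding repressors, were later in 74 of 517 cases and earlier in 4 (mean difference -0.27, permutation p = 5e-04 by circular shifts, the smallest they can give, adjusted p = 0.010). On chromosome 19, where these genes form clusters, 58 of 250 ZNF genes were later (23.2%) and 0 earlier, with a mean of -0.45, beside 76 of 1200 other genes there (6.33%). Elsewhere 16 of 267 ZNF genes were later (5.99%), beside 1201 of 18190 other genes (6.6%). In beta-like cells 56 ZNF genes were earlier and 86 later (adjusted p = 0.54).

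Keratin genes, which encode filaments of epithelial cells, were earlier in 25 of 55 cases in definitive endoderm (mean 0.64, adjusted p = 0.17) and in 41 of 55 in beta-like cells (mean 1.01, adjusted p = 0.13), so the family did not pass the test over clusters in either. The called genes in beta-like cells were 20 of 27 on chromosome 12 (52168996 to 52952906) and 21 of 28 on chromosome 17 (40654665 to 41624575). Core histone genes of the large cluster on chromosome 6 (25726063 to 27893891) were later in 40 of 49 cases in beta-like cells, their median going from -0.54 in ESC to -1.15 (adjusted p = 0.50 for the family). Of the UGT genes, enzymes of drug and bilirubin conjugation, the 9 in 1 region of chromosome 2 (233617633 to 233773300) were earlier in beta-like cells (mean 1.47), while 3 of 11 on chromosome 4 were later (mean -0.47; adjusted p = 0.54 for the family). Genes of such clusters lie close together and share much of their value, so each cluster is a regional change and not a set of separate ones.

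Chromosomes differed in how their windows moved in beta-like cells. On chromosome 22, 17.6% of windows were earlier and 1.11% later, and on chromosome 15, 24.6% and 6.91%. On chromosome 4 the shares were 6.46% and 21.4%, and on chromosome X 6.58% and 18.4%. In definitive endoderm 0.413% of windows of chromosome 19 were earlier and 8.76% later.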
